A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

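Total RNA of Saccharomyces cerevisiae was measured on Affymetrix Yeast Genome arrays, with 2 arrays of the wild type and 2 of the Sen1ΔN strain. Per the labels, cultures were started at an OD600 of 0.4 in synthetic complete medium with 2% glucose, grown with shaking at 24 °C and harvested at an OD600 of 1.5, and 6 ug of total RNA went into each biotin labelling reaction. The 2 arrays of a strain come from independent experiments, per the series' design text. Groups and replicate numbers were taken from the sample titles.

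The deposited values are on the log2 scale, 1 value per probe set and array. The submitters' processing notes name RMA and Affymetrix Expression Console, with no version given in the sources used here. RMA, by its published design, subtracts background, sets the arrays to a common distribution and summarises the probes of a probe set. Which arrays were normalized together is not stated, and scanner files were not used here. The values ran from 2.47 to 14.7, and the median over the yeast genes lay between 10.51 and 10.53 on the 4 arrays, so no further normalization was applied. A common distribution hides a change in the total amount of mRNA per cell, and log2 differences of signal understate changes near the background and near the top of the scale.

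Of the 10928 probe sets, 7244 carried 1 annotated gene, 5498 of them from S. cerevisiae and 1746 from the fission yeast S. pombe. One probe set named several genes and 3683 had no annotation, among them 166 Affymetrix controls and 47 reporter probe sets. Names were updated through the R64 reference table for 12 probe sets. The mean was taken over the probe sets of a gene for the 47 genes with 2 or more, which left 5449 genes. No yeast RNA should pair with the S. pombe probe sets, and their 95th percentile on each array (5.26, 5.24, 5.36 and 5.35 log2) served as the background level. Between 97.9% and 98.3% of the yeast genes lay above it. A gene at or below this level on both arrays of a strain has only a bound there, given as "at least" a fold, with the background level in place of any lower value. The number of arrays limits the precision of every value.

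The difference Sen1ΔN minus wild type was fitted for each gene with limma 3.58.1 (lmFit and eBayes without trend) in R 4.3.3, two-sided, with 2 residual degrees of freedom and Benjamini-Hochberg adjustment over the 5449 genes. A gene was called at an adjusted p under 0.05, and a second count also required a log2 difference of at least 1. An exact permutation test of 2 arrays against 2 cannot go below p = 0.33, so the small p-values of limma rest on the spread shared across genes. The p-values measure the spread between 2 cultures of a strain. In 10 simulated data sets of 5449 genes, 200 genes each were changed. The test recovered 48.8% of changes of 0.5 log2, 81.8% of changes of 1 and 95.6% of changes of 2. Of its calls, 4.6% fell on unchanged genes. In the data 3796 of 5449 genes were called, so these rates do not carry over to this comparison.

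Before the data were examined, 59 gene lists were fixed, of which 56 had at least 5 measured members. These were tested with camera at a preset correlation of 0.01, two-sided, adjusted over the 56 lists. In simulated data with independent genes, which says nothing of correlated ones, camera called 10 of 10 planted lists and 0 of 400 unchanged lists. The list of genes downstream of snoRNA genes holds the next protein-coding gene on the same strand within 1000 bp, from gene order in the R64 reference table. A gene that overlaps the snoRNA gene, such as a host gene, was passed over. The snoRNA genes were not sorted by how they are transcribed or terminated. No coordinates are printed, since the build behind the array is not given in the sources used here. The rule for named genes was also fixed then. It takes the 12 largest rises and 12 largest falls among called genes whose arrays separate by strain, with a standard name and without Ty, YRF1 or dubious ORFs. It adds SEN1, the marker genes and the mating-type genes, up to 4 members with the largest difference of each called list, and up to 3 of the lists on antioxidant defence, respiratory chain, TOR, Sen1 and RNA surveillance, attenuated mRNAs and snoRNA neighbours.

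The alternatives were a replicate block, leaving out each array, quantile normalization of the yeast genes, centring each array on their median, leaving out genes above background on fewer than 2 arrays, eBayes with trend and robust moderation, the brightest probe set per gene and an unmoderated linear model. For lists they were camera with an estimated correlation, fry, and lists without the marker and mating-type genes. Chosen after seeing the control probe sets were a test of genes shorter than 1000 bp alone, and removal of a loess trend (span 0.5, degree 1) of the log2 difference on gene length, also with camera at an estimated correlation. Gene length is the span in the reference table, introns included. Permutation tests between sets of genes used 100000 resamples in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, two-sided, and treat genes as units, which are not independent replicates.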

Results

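Transcript levels were compared between exponentially growing wild-type yeast and a strain whose Sen1 protein lacks part of its N terminus (Sen1ΔN). Sen1 is a nuclear helicase that acts with the RNA-binding proteins Nrd1 and Nab3 in ending transcription of snoRNA genes and other non-coding RNAs. Each strain had 2 arrays from independent cultures. Replicate arrays correlated at r = 0.997 in the wild type and 0.993 in Sen1ΔN, across genes, and arrays of different strains at 0.864 to 0.878. The strains are not isogenic by their labels. The wild type is BY4741, a MATa laboratory strain with deletions in HIS3, LEU2, MET17 (also called MET15) and URA3. The Sen1ΔN strain is MATα, with alleles in ADE2, HIS3, LYS2, TRP1 and URA3, and its sen1 allele is written together with the LEU2 locus. Every difference below is therefore one between the arrays of these 2 strains, in which SEN1 and background change together. A 3′ minus 5′ shift of control transcripts, given below, follows strain as well. Technical differences between the arrays can thus not be told apart from strain by design.

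The comparison asked how basal expression differs in Sen1ΔN, a strain studied for redox balance, mitochondrial function and TOR signalling. Genes of mitochondrial energy production, stress defence and amino acid uptake were lower in Sen1ΔN, while genes of ribosomes, purine synthesis and genes lying behind snoRNA genes were higher. In limma, 3796 of 5449 genes (69.7%) passed an adjusted p of 0.05, of which 1921 rose and 1875 fell. At least 2-fold changes numbered 470 rises and 617 falls. The median absolute difference between the strains was 0.46 log2, against 0.07 between wild-type replicates and 0.11 between Sen1ΔN replicates. An unmoderated linear model called 2445 genes, 941 of them at least 2-fold. Of the 56 gene lists tested, 28 were called, 11 up and 17 down. With an estimated correlation, which rests on 4 arrays, no list was called, and the smallest adjusted p over all lists was 0.417. Camera then tests on the 2 residual degrees of freedom, so hardly any list could pass. The list of MATa-specific genes had an adjusted p of 0.000129 at the preset correlation of 0.01. It had 0.417 at its estimated correlation of -0.012. This setting therefore cannot tell whether correlation between genes accounts for a call. Estimated correlations of the called lists ran from -0.063 (ATP synthase) to 0.707 (Gcn4 targets). The estimate was 0.512 for general stress genes and 0.468 for ribosome biogenesis. Where a list's correlation lies far above the preset 0.01, its camera p-value at the preset may be too small.

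The SEN1 transcript (YLR430W) was 2.78-fold higher in Sen1ΔN. Its log2 signal was 10.66 and 10.57 on the wild-type arrays and averaged 12.09 on the Sen1ΔN arrays, a rise of 1.47 (SE 0.09, n = 2 arrays per strain, limma adjusted p = 0.000239). The position of its probe set relative to the truncated part is not known here, so this value does not check the truncation. The marker genes differed in both directions. MET17, needed for methionine synthesis, lay at background in the wild type and at 12.11 in Sen1ΔN, at least 116-fold higher. URA3 lay at background in the wild type and was at least 6.72-fold higher in Sen1ΔN. LEU2 rose by 6.15 log2 (SE 0.07) from 6.04 to 12.19, although the Sen1ΔN label carries a leu2 deletion. HIS3 fell by 5.81 (SE 0.16), from 11.93 and 11.94 on the wild-type arrays, although the wild-type label carries a his3 deletion. LYS2 fell by 1.43 (SE 0.24) and lost the call in the unmoderated model (adjusted p = 0.0915). ADE2 did not pass the test, with a difference of 0.12 (SE 0.10). It was -0.004 without Sen1ΔN replicate 1 and 0.237 without replicate 2, where it passed (adjusted p = 0.0469). As a list, the markers were not called (camera adjusted p = 0.347, 3 rose and 2 fell of 6 measured).

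The mating-type genes separated the strains on every array. All 7 genes specific to MATa cells fell, with a median of -4.18 log2. The log2 difference was -5.25 for BAR1 (SE 0.25), which encodes the protease that degrades α-factor, -5.05 for the receptor gene STE2, -4.60 for MFA2, -4.18 for MFA1, -3.70 for AGA2 and for ASG7, and -2.91 for STE6. All 6 measured genes specific to MATα cells rose, with a median of 3.34. They were HMLALPHA1 (at least 164-fold, from background), MF(ALPHA)2 (6.97 log2), the agglutinin gene SAG1 (3.70), the receptor gene STE3 (2.98), AFB1 (2.45) and MF(ALPHA)1 (2.01). HMRA1 fell at least 29.8-fold, to background. HMLALPHA1 and HMRA1 have copies of the same sequence at the mating-type locus, which their probe sets do not tell apart. The camera adjusted p was 0.000129 for the MATa list and 0.000252 for the MATα list, and 0.417 for each with an estimated correlation. Pheromone-induced genes were also higher, with 10 of 14 rising and 1 falling (adjusted p = 0.00675, and adjusted p = 0.417 with an estimated correlation). PRM3 rose by 3.48, PRM6 by 2.10 and FIG2 by 1.54, whereas PRM8 fell by 1.53. Counts adjusted over the list alone were the same for these 3 lists and the markers. Genes expressed in both haploid types went both ways (3 rose and 2 fell of 9, adjusted p = 0.983), and so did genes of meiosis (9 rose and 6 fell of 16, adjusted p = 0.516).

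**Figure D1:**
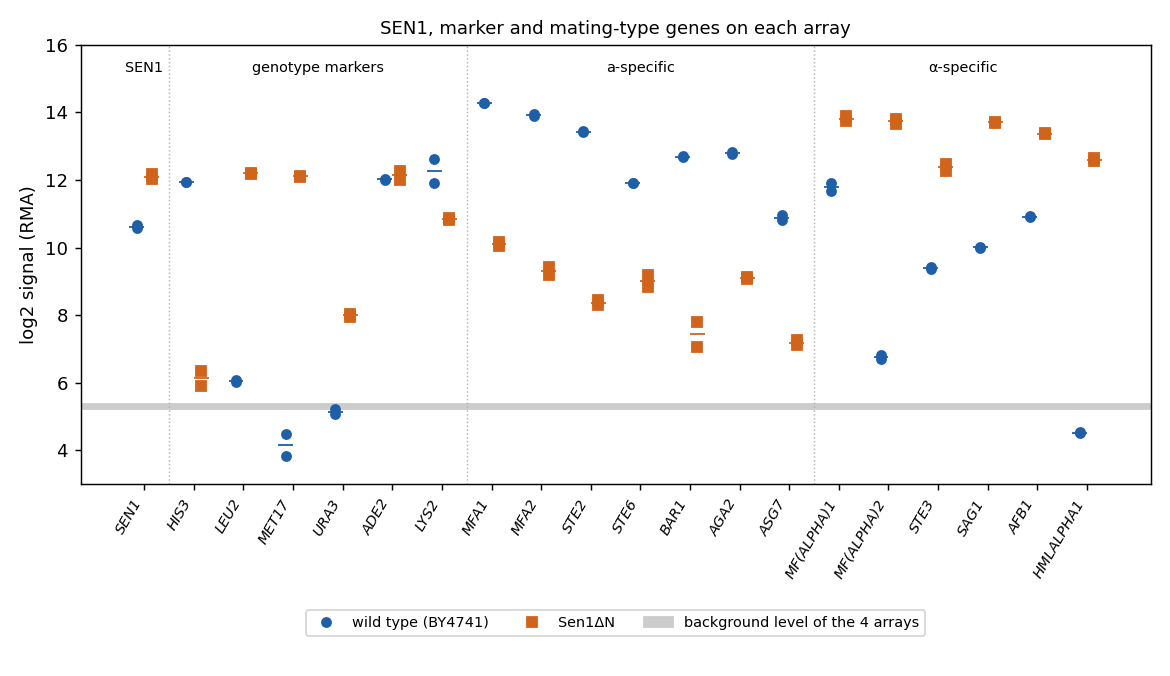
Log2 signal of SEN1, the auxotrophic marker genes and the mating-type genes on each array; points are single arrays, short lines the mean of 2 arrays of a strain, and the grey band the background level of the 4 arrays. MET17, URA3 and HMLALPHA1 lie at background in the wild type, and all 7 a-specific genes are lower and all 6 α-specific genes higher in Sen1ΔN.

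Beyond mating type and markers, the largest falls began with ASP3-1 and PHO84. The signal of ASP3-1, one of the identical genes for cell-wall asparaginase, fell at least 169-fold to background. Whether this locus and those named next are present with the same sequence in both strains is not known here. The phosphate transporter gene PHO84 fell by 5.79 log2 (SE 0.07). The other falls were in HAC1, the transcription factor of the unfolded protein response (-5.15), VEL1 (-5.12), the aquaporin gene AQY2 (-5.09), the formate dehydrogenase gene FDH1 (-4.95), GND2, the gene of a phosphogluconate dehydrogenase (-4.72), and the phosphatase gene PTC2 (-4.67, SE 0.30). The largest rises included CTO1 (4.12 log2, SE 0.08), CYC7, an isoform of cytochrome c (3.64, SE 0.22), MET32, a transcription factor of sulfur metabolism (3.63), USE1, a SNARE gene (3.62), and RGI2 (3.46, SE 0.51). SAE3, a gene of meiotic recombination, was at background in the wild type and rose at least 5.38-fold. Without Sen1ΔN replicate 1 the difference of RGI2 was 4.24, and without replicate 2 it was 2.68. Of these, SAE3 and RGI2 lost the call in the unmoderated model (adjusted p = 0.0508 and 0.0803). Among the 12 largest rises and 12 largest falls, mating-type and marker genes included, the largest limma adjusted p was 0.00331. Over all 126 genes named by rule, the SE ranged from 0.06 to 0.51 with a median of 0.09.

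The arrays also differed in a sign of RNA or label length. Control transcripts are probed near the 3′ end, in the middle and near the 5′ end. The 3′ minus 5′ difference of ACT1 was 0.25 and 0.24 log2 on the wild-type arrays and 2.48 and 3.46 on the Sen1ΔN arrays. For WBP1 it was 1.80 and 1.88 against 5.91 and 5.83. The 6 of 7 yeast controls whose 5′ signal lay above background on all arrays moved this way, with a median change of 2.38. Of the 4 Bacillus control RNAs, 2 had a 5′ signal above background on both wild-type arrays, and their difference grew by at least 1.72 and 2.52. The 5′ signals of SRB4 and of the other Bacillus RNAs lay at background on a wild-type array, so no change is given for them. The 4 hybridization controls, which by the platform's design are added after labelling, differed by -0.083. Log2 differences also varied with gene length, though not steadily. The median was 0.72 in the 243 genes of up to 300 bp and -0.17 in the 1257 genes longer than 1000 and up to 1500 bp. In longer genes it lay near 0, at -0.034 up to 2000 bp, 0.004 up to 3000 bp and 0.002 above that. Removing this trend left 3761 genes called, 975 of them at least 2-fold, and 857 of these were among the 1087 of the unadjusted values. Where it ended the call of a list, its value stands beside that list.

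**Figure D2:**
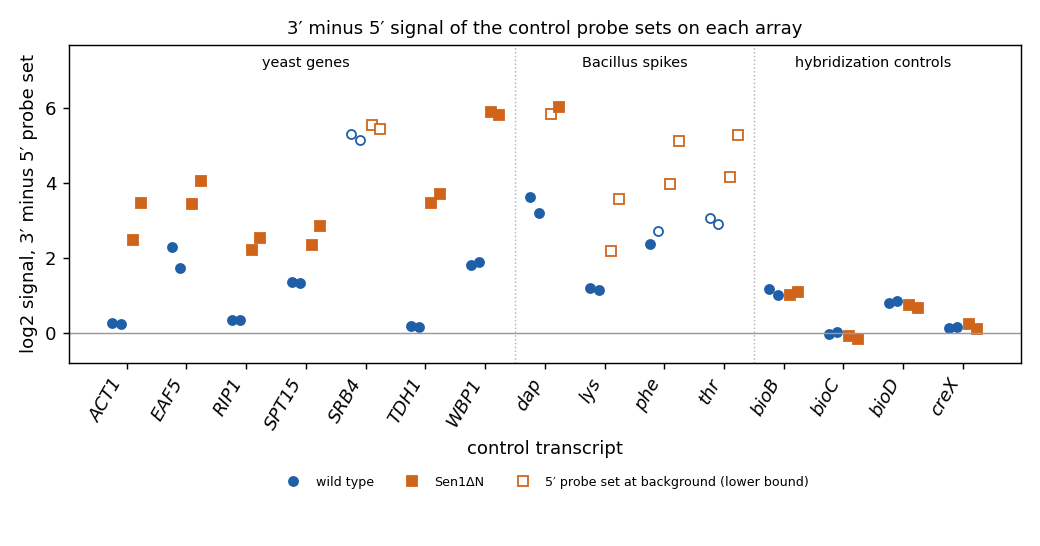
Log2 signal of the 3′ probe set minus that of the 5′ probe set for each control transcript, with 1 point per array; open points are lower bounds, with the background level in place of a lower 5′ signal. The 6 yeast controls drawn with filled points alone lie higher on the Sen1ΔN arrays, by a median of 2.38, and the hybridization controls do not.

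Genes of stress defence were lower in Sen1ΔN. Of 36 genes of the general stress response driven by Msn2 and Msn4, 29 fell and 3 rose, with a median of -1.02 log2. The differences were -4.72 for GND2, -3.02 for the catalase gene CTT1 (SE 0.14) and -2.66 for the phosphoglucomutase gene PGM2 (SE 0.21), while TMA10 rose by 1.95 (SE 0.23, adjusted p = 0.0602 in the unmoderated model). Heat shock genes fell in 20 of 26 cases and rose in 2. The small chaperone gene HSP26 fell by 4.39 (SE 0.07), and the differences of SSA4, HSP82 and HSP78 were -2.81, -1.81 and -1.69. Among 35 antioxidant genes, many of them targets of Yap1, 19 fell and 7 rose. The differences were -3.02 for CTT1, -3.01 for the peroxiredoxin gene TSA2, -2.19 for the cytochrome c peroxidase gene CCP1 and -1.68 for SOD2, the mitochondrial superoxide dismutase gene. Adjusted over the list alone, 30 general stress genes and 21 heat shock genes fell, and the other counts were the same. The camera adjusted p was 1.31e-05 for general stress, 0.000129 for heat shock and 0.0255 for antioxidant genes. With an estimated correlation the adjusted p was 0.753, 0.417 and 0.417. Among genes shorter than 1000 bp alone, the 6 heat shock members gave an adjusted p of 0.499, at a median of -0.089 against -0.86 for the whole list. The 11 general stress genes of that length had a median of -0.59 and the longer ones of -1.21. The 3′ minus 5′ shift of the controls lay on the same arrays.

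Stores and side routes of carbon metabolism moved the same way. Of 17 genes of trehalose and glycogen metabolism, 14 fell and 1 rose (adjusted p = 0.00249, and adjusted p = 0.695 with an estimated correlation). The glycogen phosphorylase gene GPH1 fell by 1.66, the glycogen synthase gene GSY2 fell by 1.63, and GLG1 rose by 1.44 (adjusted p = 0.0685 in the unmoderated model). Of 11 genes of the pentose phosphate pathway, 10 fell and 1 rose (adjusted p = 0.00183, and adjusted p = 0.417 with an estimated correlation). The largest falls were in the minor isoforms GND2 (-4.72), TKL2 (-3.58) and NQM1 (-2.21) and in SOL4 (-1.82). TKL2 lies next to LYS2, a marker of the Sen1ΔN strain. Glycolytic and fermentative genes fell in 8 of 16 cases, none of them 2-fold, with a median of -0.20. PDC5, ENO1, TDH1 and PGI1 differed by -0.93, -0.79, -0.76 and -0.45. The adjusted p was 0.0113 for this list, 0.417 with an estimated correlation and 0.168 with the length trend removed, at a median of -0.092. Counts adjusted over the list alone were the same for the 3 lists.

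Nuclear genes of mitochondrial energy production were lower. In the tricarboxylic acid cycle, 14 of 16 genes fell and 1 rose, with a median of -0.81. The succinate dehydrogenase genes SDH1, SDH2 and SDH4 differed by -2.17, -1.93 and -1.39 (SE 0.09, 0.07 and 0.07), and the fumarase gene FUM1 fell by 1.69. Of 27 respiratory chain genes, 15 fell and 4 rose. QCR2, a subunit of complex III, fell by 2.15, against the rise of CYC7 by 3.64. ATP synthase genes fell in 11 of 15 cases and none rose. ATP2, ATP3 and ATP5 differed by -1.68, -1.65 and -1.49, and the inhibitor gene INH1 fell by 1.32. Counts adjusted over the list alone were the same. The camera adjusted p was 0.000861, 0.022 and 0.00511, and the adjusted p with an estimated correlation was 0.417, 0.753 and 0.417. Quantile normalization of the yeast genes ended the call of the respiratory chain (adjusted p = 0.0801). On these arrays the 5′ control signal of RIP1, itself a complex III gene, differed by -2.93 and its 3′ control signal by -0.89. In the gene comparison RIP1 differed by -1.63, between these values. There ACT1, TDH1 and WBP1 differed by -0.18, -0.76 and -0.22, close to their 3′ control signals (-0.16, -0.62 and -0.19).

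In contrast, genes of both ribosomes were higher. Of 127 cytosolic ribosomal protein genes, 94 rose and 3 fell, with a median of 0.32 log2, and 3 rose at least 2-fold: RPL22B by 1.32 (SE 0.07), RPS14B by 1.17 (SE 0.13) and RPL4B by 1.06 (SE 0.13, adjusted p = 0.0531 in the unmoderated model). RPL41A rose by 0.79, and with the length trend removed it turned to -0.21 and lost its call (limma adjusted p = 0.0553). Mitochondrial ribosomal protein genes rose in 40 of 67 cases and fell in 7, with a median of 0.45. MRPL37 rose by 1.52, MRPS8 by 1.39 and MRPL32 by 1.29, and MRPL4 fell by 1.89 (SE 0.27, adjusted p = 0.0755 in the unmoderated model). Of 71 ribosome biogenesis genes, 36 rose and 5 fell. LOC1 rose by 1.27, NOP7 by 1.06 and DBP10 by 1.04, and NOP1, which encodes fibrillarin, fell by 1.04. Adjusted over the list alone, 96, 41 and 35 genes rose, and the numbers of falls were the same. The camera adjusted p was 6.71e-09, 0.000252 and 0.0033, and the adjusted p with an estimated correlation was 0.417, 0.417 and 0.761. Among the 22 biogenesis genes shorter than 1000 bp it was 0.41 with the preset correlation, at a median of 0.30 against 0.33 for the whole list; all genes of that length had a median of 0.15. Subunits of RNA polymerase II rose in 10 of 12 cases, also adjusted over the list alone, and none reached 2-fold. RPB4 rose by 0.98, RPO21, the gene of the largest subunit, by 0.76, RPB10 by 0.72 and RPB7 by 0.70 (adjusted p = 0.0709 in the unmoderated model). The adjusted p was 0.00645, 0.639 with an estimated correlation and 0.166 with the length trend removed, at a median of 0.15 against 0.57 before. RPB10 alone then differed by 0.022. These are lists of short genes, with a median length of 771 bp for cytosolic ribosomal proteins, 714 bp for mitochondrial ones and 530 bp for polymerase II, and short genes lay higher on the Sen1ΔN arrays in general.

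Amino acid permease, nitrogen catabolite, Gcn4, branched-chain and phosphate genes were called lower as lists, whereas the arginine, lysine, sulfur, hexose, iron and zinc lists were not called. With an estimated correlation none of these was called, with adjusted p = 0.55, 0.417, 0.761, 0.761 and 0.558 for the lists called lower. Lysine passed without wild type replicate 1 (adjusted p = 0.0162) and zinc without Sen1ΔN replicate 1 (adjusted p = 0.0447), both lower, and with an estimated correlation over all arrays their adjusted p was 0.855 and 0.761. Of 14 amino acid permease genes, 13 fell and 1 rose (adjusted p = 0.000774). The general permease gene GAP1 fell by 2.57 (SE 0.10), and the differences of AGP1, the methionine permease gene MUP1 and the proline permease gene PUT4 were -2.19, -1.66 and -1.52. Genes under nitrogen catabolite repression fell in 17 of 24 cases and rose in 5 (adjusted p = 0.0121). Among them CAR2, of arginine breakdown, fell by 2.72 and DAL3 fell by 1.46. Of 44 amino acid synthesis genes controlled by Gcn4, 22 fell and 4 rose (adjusted p = 0.0034). Besides the marker HIS3, these included LEU1 (fell by 1.74), BAT1 (fell by 1.64) and ARG4 (fell by 1.56). The branched-chain list had 9 falls and 2 rises of 12 (adjusted p = 0.0364), with OAC1 at -1.63 against the rise of the marker LEU2. Its adjusted p was 0.0542 without wild type replicate 2, and fry turned its direction. Of 15 phosphate-regulated genes, 9 fell and 2 rose (adjusted p = 0.0317). After PHO84 these were GIT1 (fell by 3.35), PHM6 (fell by 2.03) and the acid phosphatase gene PHO5 (fell by 1.68). Among members shorter than 1000 bp the adjusted p was 0.379, at a median of -0.21 against -0.85 for the whole list. Adjusted over the list alone, 6 nitrogen genes rose, and 21 Gcn4 targets, 10 branched-chain genes and 10 phosphate genes fell; the other counts were the same.

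Purine and one-carbon genes went the opposite way, with 11 of 16 rising and 1 falling (adjusted p = 0.00511, and adjusted p = 0.639 with an estimated correlation); 2 fell adjusted over the list alone. The glycine cleavage genes GCV2 and GCV1 rose by 2.56 and 2.15 (SE 0.07 and 0.08), MTD1 by 2.30 and ADE17 by 2.05. The Sen1ΔN label carries an ade2 allele, and the wild-type label names none. Copper-related genes rose in 3 of 5 cases, namely FRE7 (2.09), the metallothionein gene CRS5 (1.78) and CTR3 (0.53), while CTR1 differed by 0.24 and did not pass. CTR3 lost the call in the unmoderated model (adjusted p = 0.0587), and CTR1 passed without Sen1ΔN replicate 1 (adjusted p = 0.0179) and with the length trend removed (0.0122). The adjusted p of this list was 0.0473, 0.55 with an estimated correlation, 0.053 after quantile normalization, 0.0565 without Sen1ΔN replicate 2 and 0.253 with the length trend removed. With that trend removed its median was 0.56, against 0.53 before, and its mean 0.74, against 0.96 before. A replicate block also ended the call of the copper list (camera adjusted p = 0.0564). Of the 5 genes on the flocculin list, 4 rose (adjusted p = 0.0418, and adjusted p = 0.55 with an estimated correlation). They were FLO1 (2.66), FLO9 (1.14), FLO10 (0.57) and FLO8 (0.28), which encodes a regulator of flocculin genes and not a flocculin. FLO8 lost its call without wild type replicate 1 (adjusted p = 0.0659), without wild type replicate 2 (0.138) and in the unmoderated model (0.0532). The call of the list ended without Sen1ΔN replicate 1 (adjusted p = 0.0575), after quantile normalization (0.0505) and with trend and robust moderation (0.0534). These FLO genes include near-identical copies, which probe sets share in part. For cell wall genes, 14 of 21 fell and 4 rose (adjusted p = 0.0215, and adjusted p = 0.417 with an estimated correlation), with YPS3 at -2.96, the glucan synthase gene GSC2 at -1.95, and SVS1 and PIR3 at -1.45 each. Adjusted over the list alone, 5 rose. Among members shorter than 1000 bp the adjusted p was 0.147, at a median of -0.28 against -0.49 for the whole list. Proteasome genes fell in 16 of 33 cases and rose in 2 (adjusted p = 0.015, and adjusted p = 0.761 with an estimated correlation). RPN10, PUP1, RPT5 and RPN7 differed by -1.42, -1.12, -0.83 and -0.56, and RPN7 lost the call in the unmoderated model (adjusted p = 0.0561). Quantile normalization gave an adjusted p of 0.29 for this list and removal of the length trend 0.137, at a median of -0.16 against -0.23 before. Copper, flocculin and proteasome counts adjusted over the list alone were the same.

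**Figure D3:**
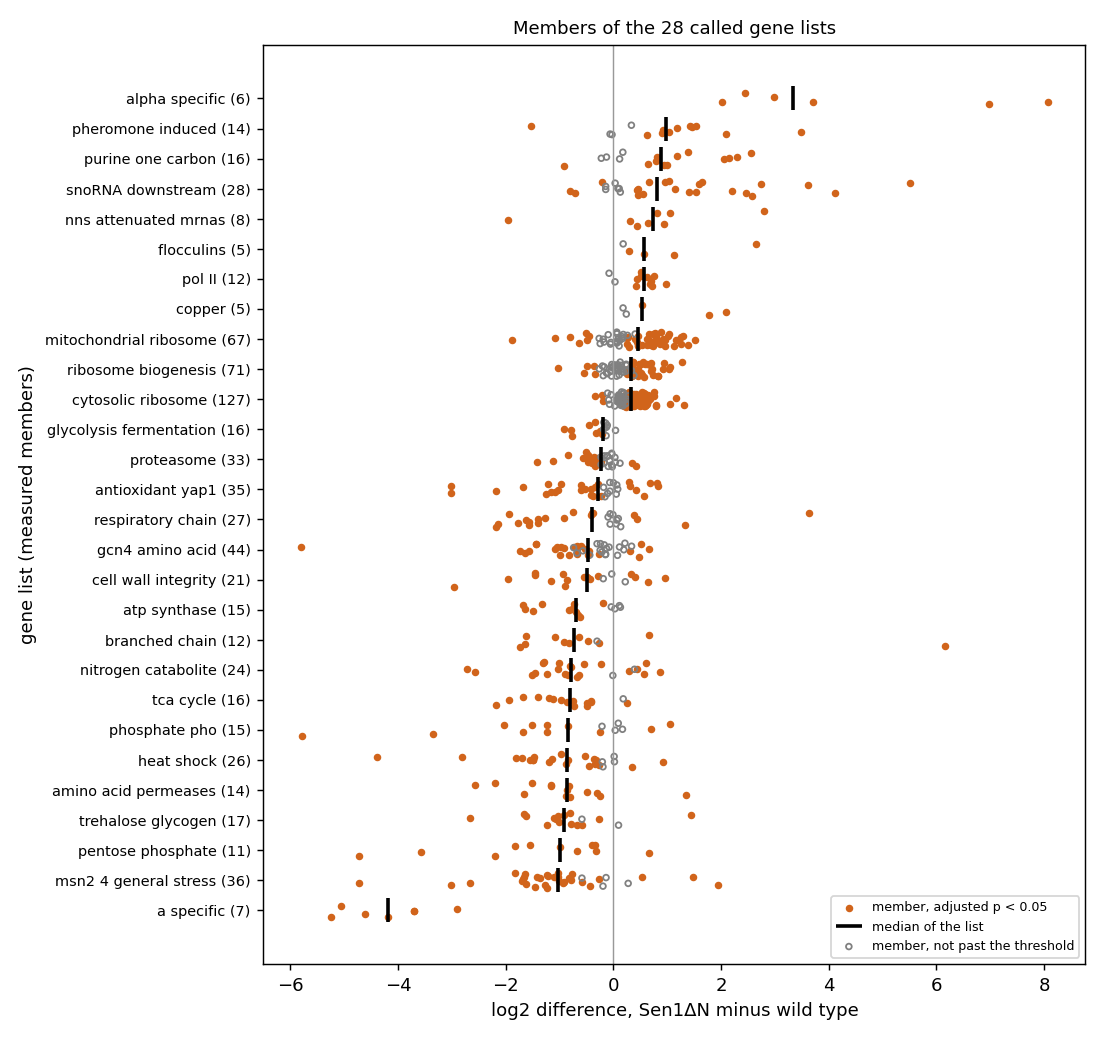
Log2 difference Sen1ΔN minus wild type for each measured member of the 28 called lists, ordered by median (black bars), with the number of members in brackets. The a-specific and α-specific lists lie farthest out, at medians of -4.18 and 3.34, and stress lists lie below 0 and ribosomal lists above it.

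Genes that lie behind snoRNA genes were higher in Sen1ΔN. Of the 28 protein-coding genes that come next after a snoRNA gene on the same strand within 1000 bp, 19 rose and 3 fell, also adjusted over the list alone, with a median of 0.81 log2. In all, 13 rose at least 2-fold. YDR042C, behind SNR47, rose by 5.52 (SE 0.06), CTO1, behind SNR33, by 4.12 (SE 0.08), USE1, behind SNR82, by 3.62 (SE 0.09) and HEM4, behind SNR5, by 2.73 (SE 0.08). The camera adjusted p was 0.000314, and 0.417 with an estimated correlation. Among the 11 members shorter than 1000 bp the median was 2.47 and the adjusted p 0.115, and the longer members had a median of 0.56. The snoRNAs themselves were not analysed here. Of 8 mRNAs known to be attenuated by the Nrd1, Nab3 and Sen1 pathway, 7 rose and 1 fell, also adjusted over the list alone. IMD2, an IMP dehydrogenase gene, rose by 2.80 (SE 0.16), NRD1 by 1.06 (SE 0.09) and ADE12 by 0.94, and GSC2 fell by 1.95. The adjusted p was 0.0418, and 0.761 with an estimated correlation. ADE12 is also on the purine list, and URA2 and URA8 are on the pyrimidine list. The strains differ in their ADE2 and URA3 alleles by their labels, and a part played by these alleles was not tested.

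**Figure D4:**
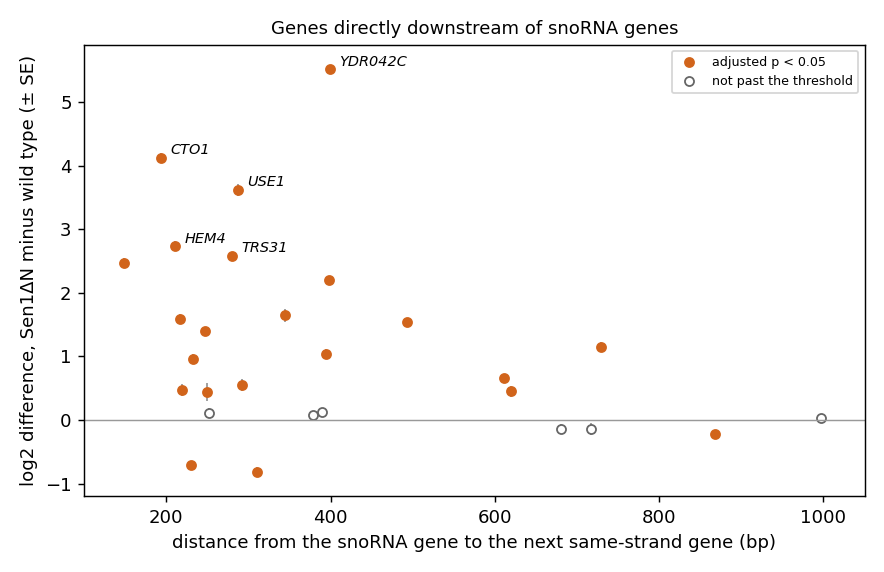
Log2 difference Sen1ΔN minus wild type (± SE from limma, 2 arrays per strain) of 28 genes against their distance from the snoRNA gene in front of them. The 13 genes at up to 300 bp have a median of 1.40 and the 15 beyond it a median of 0.45. This split was chosen after the results were seen, and the relation with distance did not pass (rho = -0.377, permutation p = 0.0501).

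The list of Sen1 partners and RNA surveillance factors was not called (adjusted p = 0.0546), with 12 of 21 genes rising and 1 falling, also adjusted over the list alone. SEN1, the exosome cofactor gene MPP6 (1.46) and NRD1 had the largest differences. The adjusted p was 0.761 with an estimated correlation and 0.173 without Sen1ΔN replicate 1. It passed without Sen1ΔN replicate 2 (adjusted p = 0.0271), with fry (0.0296) and with the length trend removed (0.0248, and adjusted p = 0.827 with an estimated correlation). TOR pathway genes were not called either (adjusted p = 0.685, 3 rose and 5 fell of 22, and 3 and 4 adjusted over the list alone). MEH1, of the vacuolar complex that activates TOR complex 1, rose by 1.34, BIT61 by 0.90, and TIP41 fell by 0.82. Its median was -0.089 and its mean 0.006. Cleavage and polyadenylation factors rose in 11 of 20 cases and fell in 5 (adjusted p = 0.298), the same adjusted over the list alone. Genes of RNA polymerases I and III rose in 10 of 19 cases and fell in 2 (adjusted p = 0.0655), the same adjusted over the list alone. They passed without Sen1ΔN replicate 2 (adjusted p = 0.0293) and after quantile normalization (0.0476), and the adjusted p was 0.761 with an estimated correlation.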

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

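The signals in the next paragraph lie in probe sets that the gene comparison does not use; the patterns of snoRNA neighbours and of ribosomal and stress genes come from that comparison. The tests of the control transcripts, of the length trend, of distance and of strain background were chosen after the results were seen, and those of opposite-strand and tandem neighbours were set before.

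The URA3 control probe set near the 3′ end was 3.83 log2 higher in Sen1ΔN (above background on 1 of the 2 wild-type arrays), which carries the ura3-52 allele where the wild type has a deletion. One of the 47 reporter probe sets rose from background to 7.80, by at least 2.56 log2, and 5 were at least 2-fold lower, the largest going from 13.09 to background, a log2 difference of -7.74 or more in size. Near the 3′ end, the Bacillus control RNAs were higher by a median of 1.80 and the hybridization controls by 1.43. The hybridization controls were also higher near the 5′ end, by a median of 1.55. The 18S rRNA control near the 5′ end was higher by 1.01. Of 3470 unannotated probe sets, 418 lay above background on at least 2 arrays. Of these, 31 were at least 2-fold higher in Sen1ΔN with no overlap between strains and 21 were at least 2-fold lower; by chance alone, 2 against 2 arrays separate in 33.3% of cases. None of the 1746 S. pombe probe sets differed 2-fold (largest 0.97; no test was run on them).

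The first pattern weighed was the weaker 5′ signal of control transcripts in Sen1ΔN. Breakdown of the yeast RNA alone was weighed with the 2 of 4 Bacillus RNAs whose 5′ signal was above background in the wild type. Their 3′ minus 5′ difference grew by a median of at least 2.12, with 3′ signals higher and 5′ signals lower. The 5′ signal of lys lay just above background in the wild type (5.59 and 5.44 log2). Its fall of at least 0.16 therefore decides little. The 5′ signal of dap fell by at least 0.78 while its 3′ signal rose by 1.74. Breakdown of the yeast RNA alone is thus argued against by dap, a single control RNA. Hybridization or scanning is argued against by the hybridization controls, whose 3′ minus 5′ difference changed by -0.083. A shorter labelled product from the Sen1ΔN samples is in line with the middle probe sets, whose change lay between the others in 8 of the 8 controls with a 5′ signal above background in the wild type and a middle signal above it on all arrays. This condition was set after it was known that 9 of all 11 controls showed that order when background was left aside, and that SRB4 and thr, which it leaves out, did not. This reading assumes that the Bacillus RNAs were added before labelling, as the platform's usual protocol has it, and whether labelling or the RNA was at fault stays open.

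For the second pattern, the rise of genes behind snoRNA genes, length dependence of the signal is argued against as the whole cause: with that trend removed the adjusted p was 9.76e-05 and the median 0.88, against 0.81 before (adjusted p = 0.454 with an estimated correlation, and 0.417 before). Among the 11 of 28 members shorter than 1000 bp, a smaller set, the call ended (adjusted p = 0.115) at a median of 2.47, and the longer members had a median of 0.56, so the rise was larger in short genes, as the trend runs, and a part played by length stays open; all genes had medians of 0.15 below and -0.070 from that length. An effect on both strands of the region is argued against by the next genes on the opposite strand. Their median was -0.033 in 26 genes (permutation p = 0.00095, BH 0.00127). Transcription running on from snoRNA genes into the next gene may contribute: the 28 genes lay above 2278 genes in tandem behind protein-coding genes, with a median of -0.039 (permutation p = 1e-05, the smallest these permutations give; BH 2e-05 over 4 comparisons), and above 124 genes behind tRNA genes, with a median of -0.024. The relation with distance across the 28 genes did not pass (rho = -0.377, permutation p = 0.0501, and r = -0.347, permutation p = 0.0669). Of 22 same-strand genes in front of snoRNA genes, 12 rose and 5 fell, with a median of 0.40. The 28 genes lay above them (permutation p = 0.0458, BH 0.0458), and 46.4% against 4.5% rose at least 2-fold. An effect on the same strand of the region therefore stays open. Strain background other than SEN1 also stays open, since 0 arrays of a SEN1+ strain with these markers were analysed here.

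The third pattern is the opposite movement of ribosomal protein and general stress genes. For general stress genes, dependence of the signal on gene length is argued against as the whole cause. Their median was -1.024 with the length trend removed and -1.023 before. This setting does not remove the weaker 5′ signal seen in the controls, so a part played by that stays open. With the trend removed, the adjusted p was 1.05e-05 for ribosomal and 2.06e-06 for general stress genes (with an estimated correlation 0.454 and 0.698, against 0.417 and 0.753 before). Within genes shorter than 1000 bp it was 2.15e-06 and 0.0156, but the trend still runs there, from a median of 0.72 at up to 300 bp to -0.046 above 750 bp. Gene length here includes introns, so for ribosomal protein genes dependence on mRNA length was not tested and stays open. The general stress median was -0.59 in short members, -1.21 in longer ones and -1.02 in all, and the ribosomal one 0.34 in short and 0.17 in longer members, both as the trend runs, so a part played by length stays open. The truncation of Sen1 and the strain background other than SEN1 cannot be told apart, with 0 arrays of a SEN1+ strain of that background. A difference in growth state at harvest was not tested.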

How the results depend on the processing

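Results are limited by 2 arrays per strain, and the short-gene and length-trend settings, the latter also with an estimated correlation (0 lists called), were chosen after seeing the data. Over the leave-one-out fits, which assume that a lone array varies like the other strain's, 2907 to 3879 genes were called, 1056 to 1138 at least 2-fold, and 27 to 29 lists; SEN1 differed by 1.40 to 1.55. The unmoderated model called 2445 genes, having no shared spread. Genes shorter than 1000 bp gave 1547 calls, 531 at least 2-fold, and 8 lists, from 2087 genes and 23 lists; SEN1 is longer. Camera with an estimated correlation, on 2 residual degrees of freedom, called 0 lists and fry 39. The other settings stayed within 1.5 times of each count, and SEN1 passed in all.

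The replicate numbers share only a name: deviations of same-numbered arrays correlated at -0.034. With a replicate block, 3471 genes were called, 1085 at least 2-fold, and 27 lists, and SEN1 differed by 1.47; copper lost its call (adjusted p = 0.0564) and no named gene did.

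Among the named genes and the 28 called lists, directions turned in 3 cases, and the cause was not tested: ADE2 to -0.004 without Sen1ΔN replicate 1, RPL41A with the length trend removed (-0.214), and the branched-chain list under fry (adjusted p = 0.958). Of the 28 lists not called, 13 turned in at least 1 setting, also for untested causes, and only haploid genes under fry and histones passed there. The adjusted p-values were, with the length trend removed, 0.0398 for histones, 0.816 for haploid, 0.439 for ergosterol, 0.981 for pyrimidine and 0.863 for TOR genes (with an estimated correlation as well, 0.538, 0.894, 0.873, 0.993 and 0.894). Under fry they were 0.0394 for haploid, 0.955 for lysine, 0.958 for gluconeogenesis and for hexose transport, 0.853 for hypoxia and 0.116 for DNA repair. After quantile normalization they were 0.598 for ergosterol and 0.982 for haploid, pyrimidine and DNA repair genes, and with trend and robust moderation 0.994 for DNA repair. Sulfur turned without marker genes (0.966), and sulfur, iron and hypoxia within short genes (0.869, 0.759 and 0.794). With 1 array left out, the ranges of the lists that turned were 0.915 to 0.957 for haploid and for hypoxia, 0.896 to 0.937 for pyrimidine, 0.665 to 0.935 for gluconeogenesis, 0.832 to 0.957 for ergosterol, 0.648 to 0.981 for daughter-specific and 0.832 to 0.944 for DNA repair genes. In all, 16 of the lists not called passed in at least 1 setting, most of them under fry, which does not compare a list with other genes.

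Of the named genes, 11 lost the call in the unmoderated model, and RPB10 and RPL41A with the length trend removed. FLO8 lost it when wild type replicate 1 or 2 was left out. CTR1 gained a call in single settings and ADE2 without Sen1ΔN replicate 2 (0.237). Fry also ended the ribosome biogenesis call (adjusted p = 0.0647). Of 5449 genes, 5377 were above background on at least 2 arrays, and 3780 of them were called.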

Other observations

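The genes in the first paragraph and the tests of chromosomes and of marker neighbours were chosen after their values were seen; the lists in the next were fixed before.

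The log2 difference between Sen1ΔN and wild type was -4.24 for BIO5 (SE 0.06), -4.03 for BIO3 (SE 0.11), -3.03 for BIO2 (SE 0.07), -2.15 for BIO4 (SE 0.10) and -2.72 for the biotin transporter gene VHT1 (SE 0.09). INO1, the inositol synthesis gene, fell by 4.09 (SE 0.07). The signal of YLR156W, which lies beside ASP3-1, fell at least 3.74-fold to background, and presence of this locus in both strains is not known here. YLL053C, which adjoins AQY2, fell by 3.04. The meiotic gene REC104 rose by 2.81 (SE 0.07).

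Of the lists not called, iron regulon genes rose in 13 of 23 cases and fell in 8 (camera adjusted p = 0.201). Genes of sulfur and methionine metabolism rose in 12 and fell in 12 of 30 cases (adjusted p = 0.971). Cell cycle genes of G1 and S fell in 8 of 13 cases and rose in 1 (adjusted p = 0.13), and those of G2 and M fell in 3 of 9 (adjusted p = 0.294). Zinc-regulated genes fell in 5 of 8 cases (adjusted p = 0.0824), and retrograde genes fell in 5 of 7 and rose in 1 (adjusted p = 0.111). Peroxisomal genes fell in 7 of 13 cases and rose in 4 (adjusted p = 0.311), autophagy genes fell in 8 of 20 and rose in 3 (adjusted p = 0.367), and subtelomeric COS genes, which are near-identical copies, fell in 4 of 9 and rose in 2 (adjusted p = 0.379). Arginine genes fell in 3 and rose in 1 of 8 (adjusted p = 0.304), lysine genes fell in 3 and rose in 1 of 9 (adjusted p = 0.398), and thiamine and vitamin B6 genes fell in 7 and rose in 4 of 13 (adjusted p = 0.382). The lists for pyrimidines (5 rose and 5 fell of 11), gluconeogenesis (4 and 4 of 16), hexose transport (6 and 4 of 14), galactose (3 and 2 of 6), ergosterol (7 and 8 of 24), hypoxia (4 and 4 of 15), daughter-specific genes (3 and 1 of 10), histones (2 and 1 of 9) and DNA repair (8 and 7 of 21) had adjusted p-values from 0.685 to 0.992. Adjusted over the list alone, 2 haploid-specific, 6 ergosterol, 1 daughter-specific and 1 histone gene rose, 5 peroxisomal genes rose, and 2 lysine genes fell; the other counts here were the same. Histones, whose direction was up at a median of 0.11 (adjusted p = 0.685), turned to a median of -0.27 with the length trend removed (adjusted p = 0.0398, and adjusted p = 0.538 with an estimated correlation). Median, mean and test differed in sign for the haploid, sulfur, pyrimidine, gluconeogenesis, hexose, TOR, ergosterol, daughter-specific and DNA repair lists, none of them called. Of the 3 lists with fewer than 5 measured members, the one of tandem copies had 3, with 1 rise and 1 fall (2 rises adjusted over the list alone); the mitochondrially encoded genes and the snoRNAs were not analysed here.

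The hypothesis of an extra or missing chromosome in Sen1ΔN is argued against, since no chromosome median exceeded 0.092 in size. DED1, next to HIS3, fell by 3.83 log2 (SE 0.20), MRM1 on its other side fell by 1.74, TKL2, next to LYS2, fell by 3.58, YCL021W-A, next to LEU2, fell by 2.98, HRI1, next to MET17, fell by 1.08, and TIM9, next to URA3, rose by 2.41. Marker alleles may affect the genes beside them, but the 12 neighbours of 6 markers, with a median absolute difference of 0.79 against 0.46 for all genes, do not settle this (permutation p = 0.0532, 20000 resamples).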
